A study of Mus musculus with 9 samples.

How the data were processed

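RNA sequencing of mouse bone marrow-derived mast cells was available as 1 table of 23951 gene symbols by 9 libraries, with 3 libraries in each of 3 groups. The groups were taken from the treatment labels of the samples, and each column of the table was matched to its sample by name. The values are FPKM (fragments per kilobase of transcript, scaled to the mapped reads of each library), as deposited by the authors. Reads were aligned with TopHat2 2.0.12 and Bowtie 0.12.7 to the mm9 mouse genome, per the submitters' processing notes. The program that computed FPKM, the gene annotation and the use of strand are not given in the sources used here. If strand was not used, reads of a gene and of an overlapping antisense gene are not separated. The values of near-identical paralogs (Tpsab1 and Tpsb2, Cyp4a12a and Cyp4a12b) are uncertain because the handling of shared reads is not known.

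FPKM values carry no read totals, so depth was estimated from the steps of the low values. Where whole reads are counted, FPKM times transcript length moves in steps worth 1 read. In 2966 genes with a single transcript of over 1000 bases in GENCODE M21 these steps put the libraries at 20.5 to 39.4 M reads. Between libraries, 53.8% to 59.8% of the ratios of values under 0.2 FPKM fell within 0.02 (log2) of a ratio of small whole numbers, where 11% would by chance. At the lowest depth, counting error alone gives a coefficient of variation of 15.6% for a gene at 1 FPKM and 4.94% for a gene at 10 FPKM, for a 2 kb transcript. These figures cover counting error only. No replicate pair looked like 1 library deposited more than once: the spread between replicates was 1.43 to 2.39 times the sampling noise, over genes with 20 to 1000 estimated reads.

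Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, which left 10890. The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 coefficient per group, an intensity-dependent prior (trend) and no covariate. All 9 libraries shared 1 estimate of the spread. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with limma's adjusted p under 0.05 were called. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, while plain folds are ratios of group means of FPKM. Errors after ± are SD over n = 3 libraries unless given as SE. No label says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

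Before the data were examined, 35 gene lists with 714 entries were fixed, covering the antigen response, mast cell genes, cell cycle, metabolism, stress and markers of other cell types. In the table, 693 entries were found, and no mitochondrially encoded transcript was among the symbols. Each of the 27 lists with 5 or more tested members was tested with camera (limma, preset correlation of 0.01, adjusted over the lists), again with a correlation estimated from the data, and with fry. The p-value could rise in the second version even where the estimated correlation was under the preset one. A call lost this way is therefore not by itself a sign of correlated members. Genes named in the text follow a rule fixed at the same time: the 10 largest rises and 10 largest falls per comparison among called genes whose groups did not overlap (chance alone separates 3 against 3 libraries completely in 10% of genes), up to 4 called members per list with the smallest adjusted p, or the 2 members with the highest FPKM where none was called, and 21 mast cell and response genes. Short RNAs were not named. Other genes are marked as chosen after their values were seen.

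The method was tested on simulated data with 200 of 10890 genes changed. The noise was normal and drawn independently for each gene. At a log2 change of 0.5 it recovered 84% of the changed genes for antigen versus IgE, 80% for IgE versus untreated and 84% for antigen versus untreated. At a log2 change of 0.25 the shares were 42%, 48% and 36%. False calls made up 5.29%, 5.88% and 3.61% of the calls. Real genes can be correlated, and 27.5% to 71.7% of the tested genes were called in the data. The simulated shares may therefore not carry over to these libraries.

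Alternatives covered the pseudocount (0.1 and 0.5), the filter, the scaling between libraries (median centring, trimmed mean, quantile), the prior, the libraries in the fit, short RNAs, a block for the replicate number, a 2-fold threshold, each library left out in turn, and the set tests. Alternatives for the X and Y chromosome values of antigen replicate 3, for leaving out IgE replicate 3 together with antigen replicate 3, and for the genes called in both steps were added after seeing the data. Symbols were matched to chromosomes through the RefSeq table of GRCm38.p6, with 145 left unmatched. Because that assembly differs from mm9, no coordinates are given. An exact 0 can be a failed estimate in such a table. The list entries at 0 in all 9 libraries numbered 34 and included Cpa3, Cma1, Malat1 and Hmgcs1, all of which are reported only as listed at 0. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for tables and figures.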

Results

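Mast cells were grown from the bone marrow of wild-type C57BL/6 mice for 4 to 6 weeks with 10 ng/ml interleukin-3 and 10 ng/ml stem cell factor, and more than 95% of them carried CD117 and the high-affinity IgE receptor, per the labels. RNA was sequenced from 3 untreated libraries, from 3 libraries of cells given 0.5 µg/ml IgE against the hapten DNP for 18 h, and from 3 libraries of cells that received this IgE and then 50 ng/ml DNP-coupled albumin for 2 h. DNP-coupled albumin is the antigen that cross-links receptor-bound IgE. Depth estimated from the steps of the low FPKM values was 29.7 to 33.5 M reads (M, mega) in the untreated libraries, 32.0 to 39.4 M in the IgE libraries and 20.5 to 28.3 M in the antigen libraries. Each library had 10190 to 10645 genes at 1 FPKM or more.

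The antigen libraries stood apart from the other 6 on the first principal component, which held 88.2% of the variance over 10488 genes. The second component, with 6.18%, separated the IgE from the untreated libraries. IgE replicate 3 lay farther from its group than any other library: its log2 differences from the mean of the other 2 IgE libraries had an SD of 0.176, against 0.105 to 0.129 in the other 8 libraries.

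**Figure D1:**
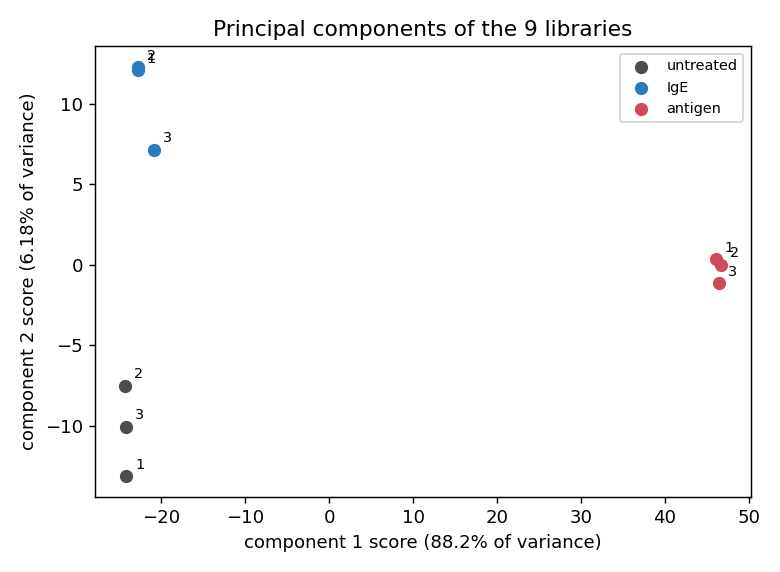
Scores of the 9 libraries on the first 2 principal components of log2(FPKM + 1), each point 1 library with its replicate number, coloured by group. The antigen libraries score 46.0 to 46.7 on component 1 and the others -24.3 to -20.9, while on component 2 the IgE libraries score 7.14 to 12.3 and the untreated ones -13.1 to -7.50.

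Some exact zeros in the table followed a library or a group. In antigen replicate 3, all 437 genes of chromosome X and all 4 of chromosome Y that were above 0 in the other 8 libraries were listed at 0, against 62 of 12969 autosomal genes. Values of X-linked genes in the antigen group are therefore also given with these zeros treated as missing, an alternative chosen after seeing the data. Counts of list members are as deposited unless stated. Eef1a1, a translation elongation factor, and Cdk8, a kinase of the Mediator complex, were listed at 0 in all 3 IgE libraries, while their means were 5562 ± 198 and 14.9 ± 0.296 FPKM in untreated and 7029 ± 195 and 37.2 ± 1.43 FPKM in antigen libraries. Ftl1, the ferritin light chain, was listed at 0 in all 3 antigen libraries, with 4342 ± 374 FPKM in untreated and 5592 ± 189 in IgE libraries. No fold is given for these 3 genes, although they are among the called ones.

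The comparison of antigen with IgE sets cells given IgE and then antigen for 2 h beside cells given IgE alone. Ccl1, a chemokine, went from 3.58 ± 0.975 to 1175 ± 75.2 FPKM, a 328-fold rise (log2 8.02, SE 0.176, adjusted p = 4.34e-09). Hdc, the enzyme that makes histamine, rose 31.2-fold from 28.7 ± 1.64 to 895 ± 28.9 FPKM (log2 4.92, SE 0.0507, adjusted p = 1.36e-10). Il13, a type 2 cytokine, rose 30.8-fold from 1.51 ± 0.310 to 46.5 ± 3.27 FPKM (log2 4.25, SE 0.135, adjusted p = 3.3e-08). Most tested genes of DNA replication and mitosis fell, 22 of 25 in the G1/S list and 23 of 25 in the G2/M list, although neither list call held with an estimated correlation (adjusted p = 0.242 with an estimated correlation for both).

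Of the 19 tested cytokine genes, 17 rose and 1 fell (camera adjusted p = 5.28e-06, and adjusted p = 0.0242 with an estimated correlation). Tnfsf14, a TNF family ligand, rose from 31.2 ± 0.596 to 346 ± 10.5 FPKM and Il1a 12.9-fold to 31.0 ± 0.797 FPKM. Tnf rose 6.63-fold to 29.8 ± 0.719 FPKM and Il6 5.89-fold to 186 ± 2.81 FPKM. Il4 rose less, from 10.1 ± 1.06 to 18.1 ± 2.26 FPKM (log2 0.79), and Csf2 from 0.581 ± 0.264 to 1.93 ± 0.341 FPKM (log2 0.90). Il3 was under the filter, with a mean of 0.0388 ± 0.0340 FPKM in antigen libraries, and was listed at 0 in the other 6. Of 12 tested chemokines, 10 rose and 1 fell (camera adjusted p = 0.000176, and adjusted p = 0.15 with an estimated correlation). Besides Ccl1, Ccl4 rose 66.4-fold to 496 ± 19.96 FPKM, Ccl3 8.27-fold to 283 ± 7.15 FPKM and Ccl2 1.98-fold to 590 ± 33.4 FPKM. Cx3cl1 went from 0.114 ± 0.0256 to 11.5 ± 0.231 FPKM.

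Transcription factors of the immediate early response rose in 24 of 26 tested members, with 1 lower (camera adjusted p = 2.58e-08, and adjusted p = 0.15 with an estimated correlation). Egr2 went from 0.144 ± 0.0266 to 52.0 ± 1.84 FPKM, Nr4a3, an orphan nuclear receptor, from 0.0210 ± 0.0235 to 23.02 ± 0.389 FPKM, Fosb to 11.7 ± 0.0615 FPKM and Atf3 to 7.11 ± 0.106 FPKM. Nr4a1 rose to 4.04 ± 0.240 FPKM (log2 1.89). Egr1 was at 3.30 ± 0.399 FPKM with IgE and 2.80 ± 0.151 with antigen (log2 -0.18, adjusted p = 0.093), a change that passed the test without IgE replicate 1 (log2 -0.26, adjusted p = 0.0199, with 0.0199 to 0.554 over the alternatives). Fos, under the filter, was at 0.215 ± 0.0919 and 0.864 ± 0.127 FPKM. Among 22 genes of the NF-kB pathway and its inhibitors, 19 rose and 1 fell (camera adjusted p = 8.11e-08, and adjusted p = 0.0242 with an estimated correlation). The inhibitors Nfkbid and Nfkbia rose 21.7-fold to 161 ± 0.474 FPKM and 7.19-fold to 96.5 ± 2.07 FPKM, and the subunits Relb and Nfkb1 rose 14.1-fold and 4.99-fold. Feedback inhibitors of MAP kinase signalling rose in 13 of 17 members and fell in 3 (camera adjusted p = 0.00119, and adjusted p = 0.11 with an estimated correlation). Gadd45b rose 92.0-fold to 148 ± 0.0920 FPKM. Dusp5, a phosphatase of ERK, rose 23.2-fold and Errfi1, an inhibitor of EGF receptor kinases, 9.16-fold. Regulators of RNA decay rose in 11 of 16 members and fell in 1 (camera adjusted p = 0.0045, and adjusted p = 0.459 with an estimated correlation), including Zc3h12c (5.73-fold), Btg1 (3.33-fold) and Rc3h1 (3.28-fold).

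Granule protease and amine storage genes rose in 16 of 21 members and fell in 2 (camera adjusted p = 0.00203, and adjusted p = 0.415 with an estimated correlation). Tpsab1, a mast cell tryptase, rose from 3.77 ± 0.361 to 207 ± 5.35 FPKM, a value that is uncertain because reads can be shared with its paralog Tpsb2. Slc18a2, the vesicular amine transporter, rose 1.87-fold to 689 ± 37.3 FPKM and Gzmc 6.72-fold to 7.07 ± 0.486 FPKM. Genes of the unfolded protein and integrated stress responses rose in 13 of 21 members and fell in 3 (camera adjusted p = 0.00164, and adjusted p = 0.261 with an estimated correlation). Slc7a11, a cystine transporter, rose 13.9-fold, Chac1 11.9-fold and Herpud1 3.17-fold to 316 ± 0.572 FPKM. Heat shock genes rose in 7 of 11 members and fell in 0 (camera adjusted p = 0.0452, and adjusted p = 0.415 with an estimated correlation), with Bag3 4.02-fold and Hsph1 1.58-fold higher.

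In the G1/S and DNA replication list, 22 of 25 genes fell, by a list median of 0.83 on the log2 scale, and 1, Pcna, rose 1.44-fold (camera adjusted p = 3.56e-07, and adjusted p = 0.242 with an estimated correlation). Mcm3, part of the replicative helicase, went from 88.9 ± 2.24 to 49.7 ± 0.636 FPKM, E2f1 from 8.26 ± 0.395 to 3.16 ± 0.118 and Ung, a uracil DNA glycosylase, from 4.72 ± 0.188 to 0.553 ± 0.0955 FPKM. In the G2/M list, 23 of 25 genes fell and 0 rose (camera adjusted p = 1.57e-06, and adjusted p = 0.242 with an estimated correlation), among them Aurkb, from 23.2 ± 1.59 to 11.6 ± 0.0937 FPKM, and Tpx2, from 40.5 ± 1.67 to 23.3 ± 0.953 FPKM. Cholesterol synthesis and uptake genes fell in 12 of 20 members and rose in 4 (camera adjusted p = 0.0438, and adjusted p = 0.454 with an estimated correlation). Mvk and Lss fell by 1.23 and 1.03 on the log2 scale. IgE replicate 3, which lay apart from its group, is on the reference side of these values.

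The largest single falls were spread over several functions. Socs1, an inhibitor of cytokine signalling, fell from 31.6 ± 6.77 to 4.02 ± 0.481 FPKM (log2 -2.68, SE 0.151, adjusted p = 8.76e-07). Kcnj2, an inward rectifier potassium channel, fell from 5.88 ± 0.245 to 0.484 ± 0.0471 FPKM, Ppp1r3g from 5.49 ± 0.543 to 0.402 ± 0.0586, Mrvi1 from 15.4 ± 1.26 to 1.78 ± 0.122, Gp5, a platelet glycoprotein, from 55.6 ± 6.02 to 10.3 ± 0.577, BC037034 from 23.9 ± 2.48 to 3.92 ± 0.386 and Mns1 from 299 ± 19.8 to 63.3 ± 3.75 FPKM. For the X-linked D330045A20Rik and F630028O10Rik, log2 changes were -1.55 (adjusted p = 2.11e-08) and -2.12 (adjusted p = 1.72e-08) with the zeros of antigen replicate 3 treated as missing. Including the zeros, they were -2.82 (adjusted p = 0.0199) and -2.81 (adjusted p = 0.000874), and the call of D330045A20Rik was lost without IgE replicate 1, with only the 2 groups in the fit and with a pseudocount of 0.1 (adjusted p = 0.0513, 0.0508 and 0.0631).

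The IgE receptor genes moved little or fell. Ms4a2, the beta chain, fell from 1080 ± 78.5 to 626 ± 11.6 FPKM (log2 -0.78, adjusted p = 3.62e-06). Fcer1a, the alpha chain, was at 5639 ± 621 and 4816 ± 135 FPKM (log2 -0.22, adjusted p = 0.0632), and its change passed the test under 8 alternatives, among them the 3 other scalings and the fit without IgE replicate 3 (log2 -0.32, adjusted p = 0.00454, with 0.00318 to 0.307 over the alternatives). Fcer1g, the gamma chain, rose by 0.16 on the log2 scale (adjusted p = 0.00389), which became -0.03 (adjusted p = 0.676) after quantile normalization, with 0.00246 to 0.676 over the alternatives. Kit, the stem cell factor receptor, was at 433 ± 55.4 and 457 ± 14.2 FPKM (log2 0.08, adjusted p = 0.41), and without IgE replicate 3 its change was 0.19 (adjusted p = 0.0173, with 0.0173 to 0.854 over the alternatives). Rcan1, a calcineurin regulator, was at 10.97 ± 0.818 and 10.7 ± 0.314 FPKM (adjusted p = 0.649). Ptgs2, the inducible cyclooxygenase, rose from 0.0523 ± 0.00850 to 3.56 ± 0.218 FPKM.

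The other 15 tested lists did not pass camera, although single members moved both ways. Of 37 adhesion, chemokine and cytokine receptors, 22 rose and 13 fell (adjusted p = 0.0909), with Tnfrsf9 46.8-fold higher at 128 ± 1.18 FPKM, the complement receptor C5ar1 24.3-fold and the PD-1 ligand Pdcd1lg2 9.04-fold. Proximal receptor signalling had 16 rises and 8 falls in 31 genes (adjusted p = 0.243), with Lat 2.36-fold and Lyn 1.92-fold higher. Calcineurin and NFAT genes rose in 8 and fell in 3 of 16 (adjusted p = 0.179), with Nfatc1 4.24-fold and Stim2 3.26-fold higher, and glycolysis genes rose in 12 and fell in 3 of 18 (adjusted p = 0.0836). Exocytosis genes fell in 8 and rose in 5 of 17 (adjusted p = 0.189), with Unc13d, Rab3d and Rab37 changed by -0.71, -0.64 and -0.50 on the log2 scale.
Mast cell identity genes rose in 10 and fell in 9 of 27 (adjusted p = 0.998), with median and mean log2 changes of -0.02 and -0.02 where fry pointed up. Stat5a (2.29-fold) and Tal1 (1.80-fold) rose and Lmo4 fell to 15.9 ± 1.89 FPKM. The apoptosis list had 8 rises and 6 falls in 18 genes (adjusted p = 0.529), with the pro-apoptotic Bcl2l11 8.74-fold and Pmaip1 4.55-fold and the anti-apoptotic Mcl1 2.00-fold higher. SOCS and STAT5 targets rose in 9 and fell in 6 of 18 (adjusted p = 0.507), eicosanoid synthesis genes in 5 and 2 of 10 (adjusted p = 0.28), interferon-stimulated genes in 4 and 7 of 17 (adjusted p = 0.361), and ribosome biogenesis genes in 8 and 6 of 24 (adjusted p = 0.868), where the median of 0.02 and the mean of -0.01 differed in sign. Named long noncoding RNAs rose in 9 and fell in 2 of 17 (adjusted p = 0.15).

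Antigen versus IgE called 3938 genes higher and 3801 lower of 10890 tested, of which 799 rose and 346 fell at least 2-fold and 186 and 19 at least 4-fold on the log2(FPKM + 1) scale. Counts adjusted over the list alone were equal to those over all genes except for 17 rises of the granule list and 13 of the glycolysis list. With an estimated correlation, camera called 2 of the 12 lists, the cytokines and the NF-kB list. With the X and Y zeros treated as missing, 4096 genes were higher and 3944 lower, and without IgE replicate 3 and antigen replicate 3 the counts were 4036 and 3988. With these zeros missing, granule genes had 18 rises and 1 fall, and heat shock genes 8 rises. Falls then numbered 23 in the G1/S and 13 in the cholesterol list, and the other called lists had equal counts.

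The comparison of IgE with untreated cells sets cells given IgE for 18 h, without antigen, beside cells given none. Most changes were small, with a median absolute log2 change of 0.26 among called genes and 3 rises and 6 falls of at least 2-fold on the log2(FPKM + 1) scale, which understates low genes. The rises on that scale were Egr1, Scd1 and Fdps, and the falls were Cyp4a12a, Cyp4a12b, the zeros of Eef1a1 and Cdk8, and 2 short RNAs. Most tested genes of DNA replication, mitosis and cholesterol synthesis rose, although none of these 3 list calls held with an estimated correlation (adjusted p = 0.103 with an estimated correlation for each). Egr1, a growth factor-inducible transcription factor, rose from 0.266 ± 0.1001 to 3.30 ± 0.399 FPKM (log2 1.76, SE 0.0844, adjusted p = 4.38e-05). Scd1, a fatty acid desaturase, rose from 6.75 ± 0.142 to 16.7 ± 1.25 FPKM (log2 1.19, SE 0.0498, adjusted p = 2.1e-05).

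In the G1/S list 24 of 25 genes rose and 0 fell (camera adjusted p = 1.19e-19, and adjusted p = 0.103 with an estimated correlation), by a median of 0.66 on the log2 scale. Ccne1, cyclin E, went from 3.33 ± 0.158 to 7.19 ± 0.433 FPKM, Rrm2, a ribonucleotide reductase subunit, from 24.8 ± 1.89 to 45.5 ± 1.35, Mcm7 from 35.6 ± 1.97 to 58.0 ± 0.648 and Mcm3 from 59.5 ± 1.51 to 88.9 ± 2.24 FPKM. Mybl2 and Tcf19, cell cycle genes outside the list, rose 2.09-fold and 1.82-fold. In the G2/M list 23 of 25 rose and 0 fell (camera adjusted p = 4.92e-15, and adjusted p = 0.103 with an estimated correlation), with a median of 0.39 on the log2 scale and Aurkb 1.51-fold and Ccna2 1.36-fold higher. Of 3 tested erythroid markers, Hbb-bt (1.41-fold) and Tfrc (1.84-fold) also rose. Cholesterol genes rose in 18 of 20 and fell in 0 (camera adjusted p = 3.55e-14, and adjusted p = 0.103 with an estimated correlation). Fdps, farnesyl diphosphate synthase, went from 58.8 ± 3.50 to 122 ± 8.91 FPKM. Insig1 went from 45.8 ± 3.20 to 70.7 ± 2.29 FPKM, and Mvd rose 1.84-fold. Tm7sf2, a sterol reductase, rose 2.19-fold and Phgdh, of serine synthesis, 1.85-fold.

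Ribosome biogenesis genes rose in 9 of 24 and fell in 0 (camera adjusted p = 2.6e-05, and adjusted p = 0.165 with an estimated correlation), with Fbl and Nop56 both 1.29-fold higher. The stress response list rose in 11 of 21 and fell in 2 (camera adjusted p = 0.00213, and adjusted p = 0.234 with an estimated correlation), led by the chaperones Calr, from 642 ± 2.67 to 1040 ± 31.5 FPKM, Sdf2l1 (1.52-fold) and Pdia6 (1.46-fold). Heat shock genes rose in 5 of 11 and fell in 0 (camera adjusted p = 0.00697, and adjusted p = 0.248 with an estimated correlation), with Hsp90ab1 1.29-fold higher. Granule genes rose in 9 of 21 and fell in 1 (camera adjusted p = 0.0154, and adjusted p = 0.384 with an estimated correlation). Gzmb went from 1158 ± 40.01 to 1585 ± 68.0 FPKM and Ctsg from 8.34 ± 0.195 to 15.7 ± 1.56, while Slc18a2 fell from 456 ± 8.36 to 369 ± 9.67 FPKM. Glycolysis genes rose in 9 of 18 and fell in 3 (camera adjusted p = 0.0404, and adjusted p = 0.165 with an estimated correlation), with Ldha 1.27-fold higher and the glucose transporter Slc2a1 changed by -0.44 on the log2 scale.

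Receptor genes moved the other way: 18 of 37 fell and 1 rose (camera adjusted p = 0.000141, and adjusted p = 0.103 with an estimated correlation). Il4ra went from 277 ± 4.39 to 209 ± 11.97 FPKM, Il10ra from 94.4 ± 1.39 to 74.0 ± 1.48, Cd24a from 38.1 ± 2.40 to 26.9 ± 0.266 and C5ar1 from 4.74 ± 0.227 to 3.01 ± 0.323 FPKM. Mast cell identity genes fell in 9 of 27 and rose in 2 (camera adjusted p = 0.0143, and adjusted p = 0.109 with an estimated correlation), including Itgb7 and Mrgprx2, which changed by -0.34 and -0.35 on the log2 scale. NF-kB genes fell in 8 of 22 and rose in 2 (camera adjusted p = 0.0258, and adjusted p = 0.165 with an estimated correlation), with Nfkb1 at -0.25 and Birc3 at -0.31. SOCS and STAT5 targets fell in 6 and rose in 3 of 18 (camera adjusted p = 0.0404, and adjusted p = 0.298 with an estimated correlation), interferon-stimulated genes fell in 7 and rose in 1 of 17 (camera adjusted p = 0.0404, and adjusted p = 0.227 with an estimated correlation), and RNA decay genes fell in 4 and rose in 0 of 16 (camera adjusted p = 0.0404, and adjusted p = 0.494 with an estimated correlation). Their members included Il2ra at -0.51, Gbp2 at -0.43 and Btg1 at -0.48 on the log2 scale.

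Among single genes, Txnip, a glucose-responsive regulator of redox state, fell from 460 ± 20.7 to 259 ± 7.20 FPKM, Serpina3g from 92.8 ± 6.53 to 49.8 ± 1.45, Klra2 from 54.4 ± 0.930 to 31.5 ± 2.53, Timp3, a metalloproteinase inhibitor, from 8.46 ± 0.825 to 4.09 ± 0.392, Rsph9 from 14.4 ± 0.291 to 7.97 ± 0.242 and Sult1a1 from 3.27 ± 0.479 to 1.46 ± 0.183 FPKM. The paralogs Cyp4a12a and Cyp4a12b, whose reads may be shared, changed by -1.02 and -1.09 on the log2 scale. Tnf rose from 1.87 ± 0.175 to 4.49 ± 0.338 FPKM (log2 0.94, adjusted p = 0.000183) and Ccl7 1.93-fold, while Il1b fell from 22.7 ± 0.382 to 13.7 ± 1.86 and Il13 from 2.81 ± 0.669 to 1.51 ± 0.310 FPKM (adjusted p = 0.014). Ccl2 rose 1.30-fold (adjusted p = 0.014), a call lost without untreated replicate 1 (adjusted p = 0.0538, with 0.00535 to 0.0538 over the alternatives), and Il4 fell by 0.33 on the log2 scale (adjusted p = 0.044), a call lost whenever 1 of the 6 IgE and untreated libraries was left out (adjusted p = 0.0541 to 0.134, the highest without untreated replicate 3). Il6 was at 37.1 ± 3.76 and 31.5 ± 3.39 FPKM (adjusted p = 0.0869), a change that passed the test after quantile normalization (log2 -0.27, adjusted p = 0.0432, with 0.0432 to 0.226 over the alternatives). Hdc was at 27.1 ± 1.23 and 28.7 ± 1.64 (adjusted p = 0.296). Receptor chain genes did not pass the test: adjusted p was 0.967 for Fcer1a, 0.0939 for Ms4a2, 0.952 for Fcer1g and 0.706 for Kit. The change of Ms4a2 was -0.14 on the log2 scale and passed the test without IgE replicate 1 (log2 -0.19, adjusted p = 0.0344) and after quantile normalization (adjusted p = 0.0401), with 0.0344 to 0.212 over the alternatives.

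The other 13 tested lists were not called. Cytokines rose in 4 and fell in 7 of 19 (adjusted p = 0.27), chemokines in 2 and 1 of 12 (adjusted p = 0.845), immediate early factors in 4 and 3 of 26 (adjusted p = 0.681), MAP kinase inhibitors in 3 and 3 of 17 (adjusted p = 0.433), with Dusp4 and Dusp6 1.69-fold and 1.66-fold higher, and proximal receptor signalling genes in 2 and 8 of 31 (adjusted p = 0.156). NFAT genes fell in 4 of 16 (adjusted p = 0.0719), exocytosis genes rose in 1 and fell in 4 of 17 (adjusted p = 0.214), the apoptosis list in 3 and 6 of 18 (adjusted p = 0.131), and eicosanoid genes rose in 3 of 10 (adjusted p = 0.476). For chemokines and immediate early factors the median and the mean differed in sign.

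IgE versus untreated called 1575 genes higher and 1424 lower. With the X and Y zeros of antigen replicate 3 treated as missing, 1727 were higher and 1546 lower. Those zeros reach this comparison through the shared estimate of the spread. Of 338 tested X and Y genes, 1 was called as deposited and 87 with the zeros missing. Rises with the zeros missing numbered 25 in the G1/S, 25 in the G2/M, 19 in the cholesterol and 13 in the ribosome biogenesis list. They numbered 12 in the stress response, 10 in the glycolysis and 2 in the receptor list. Falls with the zeros missing numbered 11 in the identity and 2 in the granule list, and the other called lists had equal counts. Adjusted over the list alone, rises numbered 25 in the G2/M, 14 in the ribosome biogenesis and 12 in the stress response list, and receptors had 3 rises and 19 falls. Falls adjusted over the list alone numbered 11 for identity, 9 for NF-kB, 8 for interferon-stimulated, 7 for SOCS and STAT5 target, 4 for glycolysis and 3 for granule genes, and the other called lists had equal counts. Among lists not called, adjusting over the list alone gave 9 falls of cytokines, 5 rises and 4 falls of immediate early factors, 4 rises of MAP kinase inhibitors and 2 rises and 5 falls of exocytosis genes. None of the 14 list calls held with an estimated correlation, and after quantile normalization 9 lists were called. The glycolysis call was lost (adjusted p = 0.0404 and 0.165) although its estimated correlation, -0.0288, was under the preset one. The gene counts depended on the libraries in the fit: without untreated replicate 1 they were 1015 and 899, and without untreated replicate 3 the lower genes numbered 880. Both counts also fell without untreated replicate 2 (1377 and 1149), IgE replicate 1 (1194 and 1078) or IgE replicate 2 (1104 and 956). Without IgE replicate 3 the counts were 1942 and 1945, and without that library and antigen replicate 3 they were 2162 and 2054.

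**Figure D2:**
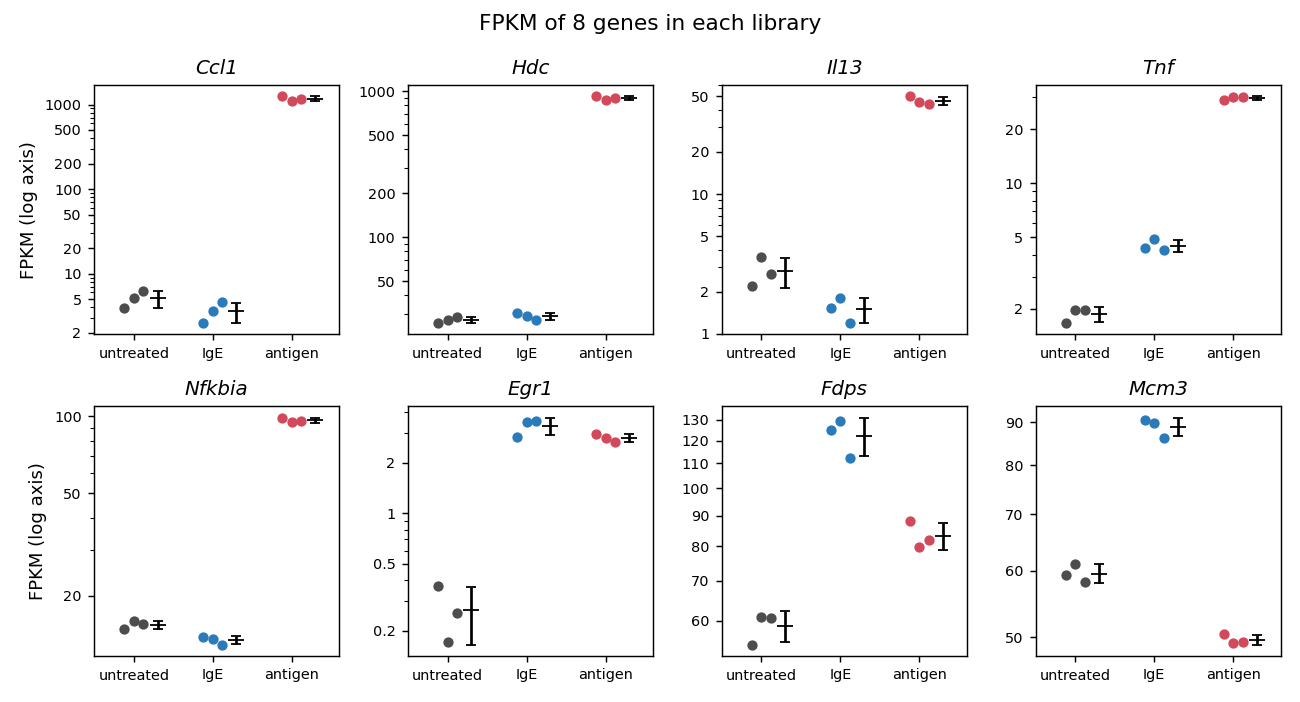
FPKM of 8 genes on log axes, with 1 point per library, grouped as untreated, IgE and antigen, and the mean ± SD of 3 libraries beside the points. Ccl1, Hdc, Il13, Tnf and Nfkbia are highest in the antigen libraries, Egr1 is higher in IgE and antigen than in untreated libraries, and Fdps and Mcm3 are highest in the IgE libraries.

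The comparison of antigen with untreated cells covers the whole treatment. Cytokine and NF-kB genes passed the list test also with an estimated correlation (adjusted p = 0.0353 for both), while the cell cycle and cholesterol lists did not pass it. Ccl1 was 229-fold, Hdc 33.0-fold and Tnf 15.9-fold higher than in untreated cells, at log2 changes of 7.60, 4.99 and 3.43. Tnfrsf12a, the TWEAK receptor, rose from 1.13 ± 0.162 to 47.7 ± 2.05 FPKM and Tnip3, an NF-kB feedback gene, from 0.678 ± 0.0492 to 31.1 ± 0.501 FPKM. Nxpe4 fell from 17.3 ± 2.90 to 2.21 ± 0.0992 and Bmf, a pro-apoptotic gene, from 7.53 ± 0.207 to 1.59 ± 0.0635 FPKM. Tfrc, the transferrin receptor, rose in both steps and ended 9.29-fold higher at 50.1 ± 1.63 FPKM.

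Camera called 10 lists, all upward. Cytokines rose in 16 of 19 and fell in 1 (adjusted p = 3.89e-05, and adjusted p = 0.0353 with an estimated correlation) and NF-kB genes in 19 and 2 of 22 (adjusted p = 6.31e-07, and adjusted p = 0.0353 with an estimated correlation). Chemokines rose in 10 and fell in 1 of 12 (adjusted p = 0.000392), immediate early factors in 23 and 1 of 26 (adjusted p = 3.44e-08), the stress response list in 17 and 0 of 21 (adjusted p = 3.89e-05) and glycolysis genes in 13 and 2 of 18 (adjusted p = 0.0338), and each of these 4 calls was lost with an estimated correlation (adjusted p = 0.145). MAP kinase inhibitors rose in 14 and fell in 2 of 17 (adjusted p = 0.000428, and adjusted p = 0.078 with an estimated correlation), granule genes in 17 and 2 of 21 (adjusted p = 0.000438, and adjusted p = 0.404 with an estimated correlation), heat shock genes in 9 and 0 of 11 (adjusted p = 0.00637, and adjusted p = 0.345 with an estimated correlation) and RNA decay genes in 9 and 1 of 16 (adjusted p = 0.033, and adjusted p = 0.587 with an estimated correlation). Trib3 (6.94-fold), Gzmb (2.28-fold) and Ctsg (3.04-fold) were among their members.

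The G1/S list had 4 rises and 13 falls in 25 genes (adjusted p = 0.131), the G2/M list 3 and 12 in 25 (adjusted p = 0.138) and the cholesterol list 12 and 5 in 20 (adjusted p = 0.173). Within them Pcna, the replication clamp, rose 2.17-fold to 350 ± 16.2 FPKM and Cyp51 2.76-fold to 73.9 ± 1.09, whereas Ung and Cdc6 fell by 1.14 and 0.63 on the log2 scale. Ms4a2 fell from 1190 ± 17.8 to 626 ± 11.6 FPKM (log2 -0.93, adjusted p = 1.22e-06), Fcer1a was at 5652 ± 281 and 4816 ± 135 (adjusted p = 0.0552, and 0.0111 without IgE replicate 3, with 0.000801 to 0.286 over the alternatives), and Kit at 447 ± 26.2 and 457 ± 14.2 (adjusted p = 0.762, with a log2 change of -0.39 and adjusted p = 0.0164 after quantile normalization, and 0.0164 to 0.948 over the alternatives). The X-linked Arhgap4 changed by -2.66 on the log2 scale as deposited (adjusted p = 0.0483), a call lost whenever 1 of the 6 untreated and IgE libraries was left out (adjusted p = 0.0665 to 0.0998). With the zeros of antigen replicate 3 treated as missing it changed by -1.17 (adjusted p = 7.3e-09). In all, 4055 genes were higher and 3750 lower, 807 and 412 of them at least 2-fold on the log2(FPKM + 1) scale, and with the X and Y zeros treated as missing 4213 and 3874. Adjusted over the list alone, heat shock genes had 10 rises, G2/M genes 10 falls, and the counts of the other 9 called lists were equal. The remaining lists did not pass camera, with adjusted p from 0.104 for ribosome biogenesis to 0.936 for SOCS and STAT5 targets. The median and the mean differed in sign for SOCS and STAT5 targets (0.01 and -0.03) and for basophil markers (-0.09 and 0.00237).

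Genes called in both steps numbered 2383. Raised by IgE and then lowered by antigen were 713 genes, where independent lists of the same sizes would share 549.7, and Rrm2, Uhrf1, Tcf19, Dscc1, Ccne1 and Fignl1 had the largest changes of this kind. Raised in both steps were 531 genes (569.5 for independent lists), including Scd1, Tnf, Phgdh, Cd68 and Mt1. Lowered by IgE and then raised were 571 (514.9), including Il1b, Il13, C5ar2 and Arrdc4, and lowered in both steps were 568 (497), including Serpina3g, Nxpe4 and Kcnj2. These examples are the genes with the largest smaller change of the 2 steps, a choice made after their values were seen. Across 10488 genes, which are not independent replicates, the log2 changes of the 2 steps correlated at r = -0.06, against -0.49 in simulated unchanged groups that share the IgE libraries, and 47.8% had the same sign against 33.3% simulated. The simulated groups hold noise only, whereas real changes move r and the share of equal signs whatever the shared libraries add. These 2 measures therefore do not show whether the steps moved alike. The covariance was more negative than simulated, -0.0085 against -0.00332, a difference of -0.00518. In 5 simulations of unchanged groups, limma called 0 genes in both steps. Few calls arise in either step where no gene is changed. These simulations therefore do not show what sharing the IgE libraries adds to the overlap of real changes. The 3 IgE libraries are too few to be split, so part of the excess of genes moving in opposite directions may come from sharing them. Without untreated replicate 1, 1565 genes were called in both steps.

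**Figure D3:**
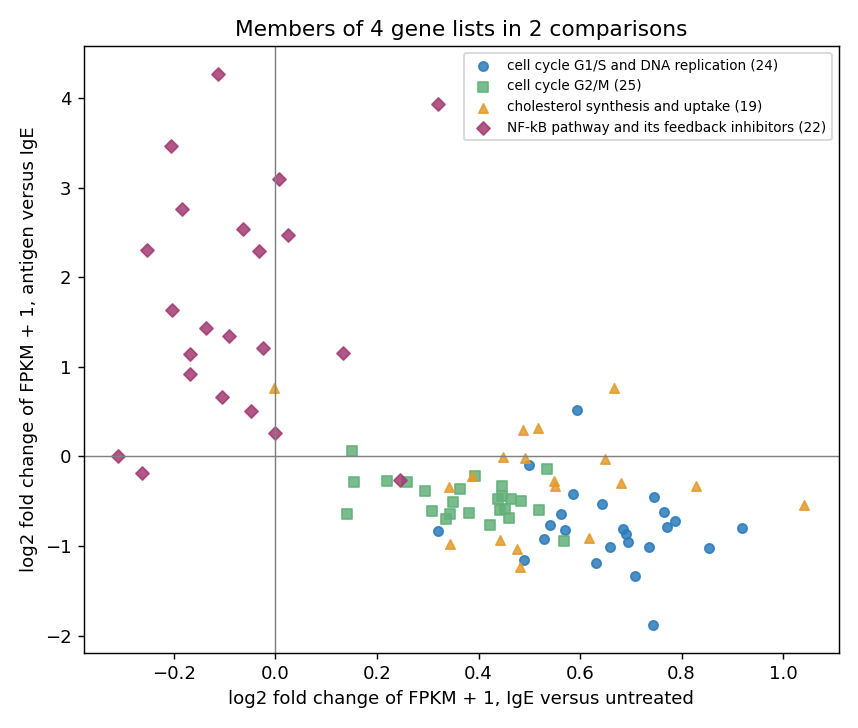
Each point is a tested autosomal member of 1 of 4 gene lists, with its log2 change of FPKM + 1 for IgE versus untreated on the x axis and for antigen versus IgE on the y axis. In the lower right part, higher with IgE and then lower with antigen, lie 23 of 24 G1/S, 24 of 25 G2/M and 15 of 19 cholesterol genes, while 20 of 22 NF-kB genes lie above 0 on the y axis. Both axes use the same IgE libraries with opposite sign, so a shift of these libraries alone would also place genes in the lower right.

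Markers of most other cell types tested were at low levels, while basophil and megakaryocyte markers included abundant transcripts. All 14 T and NK cell markers and all 10 fibroblast markers averaged under 1 FPKM, as did 12 of 14 neutrophil, 10 of 12 dendritic cell, 8 of 10 B cell, 7 of 10 eosinophil, 9 of 12 erythroid, 5 of 10 megakaryocyte and 3 of 8 basophil markers. Of 17 macrophage and monocyte markers, 9 were under 1 FPKM, while Ccr2, which fell from 73.6 ± 5.86 to 18.6 ± 0.785 FPKM with antigen, and Lyz2, from 53.8 ± 3.19 to 37.5 ± 0.263, were the highest. Of the 8 tested, 3 rose and 4 fell with antigen (adjusted p = 0.735) and 1 rose and 5 fell with IgE (adjusted p = 0.112), with Cd68 rising in both steps, from 8.62 ± 0.310 to 16.1 ± 0.245 and 30.2 ± 0.478 FPKM. Of 3 tested erythroid markers, 2 rose and 0 fell with IgE and 3 rose with antigen. Hbb-bt went from 14.96 ± 1.395 to 21.1 ± 0.817 FPKM with IgE and 25.5 ± 1.05 with antigen, the second rise being lost after quantile normalization (adjusted p = 0.0562), and Tfrc, which dividing cells also express, from 5.395 ± 0.862 to 9.93 ± 0.610 FPKM with IgE. Of the 5 tested basophil markers, 2 rose and 2 fell with antigen (adjusted p = 0.892) and 1 rose and 3 fell with IgE (adjusted p = 0.112). Ifitm1, the highest with a mean of 4843 FPKM, fell with IgE by 0.33 on the log2 scale (adjusted p = 0.0173, with 0.00672 to 0.43 over the alternatives). That call was lost without untreated replicate 1 or 3 or IgE replicate 1 (adjusted p = 0.051, 0.0583 and 0.0562). It was also lost with no filter (0.178) and with only the 2 groups in the fit (0.0619), and the change was -0.16 after quantile normalization (adjusted p = 0.43). With antigen Ifitm1 rose by 0.23 (adjusted p = 0.0262), which was -0.08 (adjusted p = 0.611) after quantile normalization, with 0.00943 to 0.611 over the alternatives. This call was also lost with no filter (adjusted p = 0.224), with a replicate block (0.0611), and without IgE replicate 1 (0.0759) or 3 (0.0526) or antigen replicate 1 (0.0554) or 3 (0.114). Il18rap rose 3.34-fold with antigen to 48.2 ± 1.63 FPKM. Prss34, a basophil protease, fell in both steps from 120 ± 11.8 to 54.7 ± 0.598 FPKM. The 5 megakaryocyte markers had adjusted p = 0.548 and 0.114. Itga2b, the highest of them, fell with IgE by 0.25 on the log2 scale, then rose by 0.13 with antigen, a direction that was -0.24 (adjusted p = 0.00334) after quantile normalization. Of 3 tested eosinophil markers, 2 fell and 1 rose with antigen. Siglec5, the symbol listed for Siglecf, rose from 0.208 ± 0.0415 to 2.80 ± 0.333 FPKM. Il5ra fell from 2.64 ± 0.167 to 0.286 ± 0.0415 FPKM and Ccr3 from 6.88 ± 0.770 to 1.46 ± 0.2502 FPKM.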

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

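The alternatives for the X and Y zeros, for leaving out 2 libraries and for genes called in both steps were chosen after seeing the data. Of 9616 values of named genes under the alternatives, 9477 kept direction and side of the threshold, 102 lost the call, 32 gained it and 5 reversed. All 5 reversals came with quantile normalization, and their cause was not tested: Fcer1g (-0.0253, adjusted p = 0.676), Ifitm1 (-0.0815, adjusted p = 0.611) and Itga2b (-0.24, adjusted p = 0.00334) for antigen versus IgE, and Fcer1g (-0.18, adjusted p = 0.0128) and Kit (-0.39, adjusted p = 0.0164) for antigen versus untreated. It also called 66 and 110 genes in the opposite direction in these comparisons, and 9 lists for IgE versus untreated. Whether more genes rose or fell depended on the scaling. For antigen versus IgE, 3309 were higher and 3994 lower after quantile normalization, 3704 and 3926 after median centring and 3862 and 3905 with the trimmed mean. For antigen versus untreated these counts were 3376 and 3894, 3808 and 3877, and 3905 and 3898. By its construction, a 2-fold threshold on the log2(FPKM + 1) scale left 799 and 346 genes for antigen versus IgE, 3 and 6 for IgE versus untreated, 807 and 412 for antigen versus untreated, and 5 in both steps. Leaving out 1 library gave 1015 to 1942 higher and 880 to 1945 lower genes for IgE versus untreated, and 1565 to 3120 genes in both steps. The lowest came without untreated replicate 1 (1015, 899 and 1565) and without untreated replicate 3 (880). An estimated correlation left 2, 0 and 2 lists for antigen versus IgE, IgE versus untreated and antigen versus untreated, and fry, which compares no list with other genes, called 25, 20 and 25. With the preset correlation and 23 other settings, the heat shock call for antigen versus IgE held in 17. For IgE versus untreated, interferon-stimulated genes held in 17, and glycolysis, SOCS and STAT5 target and RNA decay genes in 18 each. Glycolysis for antigen versus untreated held in 19, and all other calls in at least 21. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.188 to 0.132, with 1 of 9 pairs over 0.1 and 0 of 9 libraries closest to their own number. Differently numbered libraries correlated at -0.287 to 0.336, the highest for untreated replicate 1 with IgE replicate 3. A batch that does not follow the replicate number was not tested. With a replicate block, counts were 3830 and 3723, 1365 and 1135, and 3948 and 3672, with 12, 11 and 10 lists and 1961 genes in both steps. At the lowest depth, counting error is 15.6% at 1 FPKM for a 2 kb transcript, so small changes of genes near the filter are the least certain.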

Other observations

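The tests on the X and Y zeros, on Tpsab1 and on the cell cycle genes, and the counts under other groupings of the libraries, were chosen after the results were seen; the prediction on gene span was written before its result. The long noncoding RNAs named here were chosen after their values were seen, and no test compared them with other genes. Of 258 tested symbols that GENCODE M21 lists as long noncoding and RefSeq does not list as coding, antigen raised 77 and lowered 73 relative to IgE, 16 and 12 of them at least 2-fold on the log2(FPKM + 1) scale, while IgE raised 8 and lowered 51, 0 of them 2-fold on that scale, which understates low genes. A930015D03Rik rose with antigen from 4.33 ± 0.492 to 22.4 ± 0.862 FPKM, Mir22hg from 4.99 ± 0.662 to 25.1 ± 0.663 and Il1bos, antisense to Il1b, from 7.20 ± 0.302 to 22.2 ± 1.65. AU022793 fell from 7.09 ± 1.10 to 1.40 ± 0.0805 FPKM, 2610035D17Rik from 6.20 ± 0.367 to 1.29 ± 0.118 and Trp53cor1 from 6.05 ± 0.630 to 1.46 ± 0.280. E330020D12Rik fell in both steps, from 123 ± 5.80 to 82.1 ± 0.812 and 39.6 ± 1.94 FPKM. Strand is not stated, so whether reads of Il1bos and Il1b were separated is not known.

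Cell cycle genes were higher with IgE and lower after 2 h of antigen, but neither list call held with an estimated correlation (adjusted p = 0.103 and 0.242 with an estimated correlation for both lists). Both comparisons use the same IgE libraries, so a shift of these libraries alone would give both directions. For antigen versus untreated the G1/S and G2/M medians were -0.18 and -0.10 on the log2 scale (camera adjusted p = 0.131 and 0.138). The median log2 change of all tested genes was -0.00842, beside 0.66 and 0.39 for the G1/S and G2/M lists. The rises of these lists were thus not shared by the FPKM values of all genes. FPKM is scaled to the mapped reads of each library, which by itself favours a median near 0. A change in total RNA could therefore not be seen, and the median is no evidence on it. More neutrophil progenitors in the IgE libraries are argued against by Mpo, Elane and Prtn3, which reached at most 0.697 FPKM in an IgE library; the bound for this test was first set over all libraries and was restated for the IgE libraries after Prtn3 was seen at 1.13 FPKM in an untreated one. An effect of IgE, and a difference in feeding, density or handling between the groups, remain open and cannot be told apart: the labels do not describe handling, and 0 libraries are known to have been handled alike without IgE. Erythroid cells, whose markers Hbb-bt and Tfrc also rose with IgE, were not tested as an explanation.

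Tpsab1 rose with antigen while its abundant paralog Tpsb2 changed little, from 6256 ± 205 to 7420 ± 174 FPKM. If a constant share of Tpsb2 reads were counted as Tpsab1, the ratio of the genes would be equal in all groups. Tpsab1 was 0.0604 ± 0.00745% of Tpsb2 in IgE libraries and 2.80 ± 0.0558% in antigen libraries, and the lowest antigen value was 40.6 times the highest IgE value. A response of Tpsab1 itself to antigen remains a hypothesis, and a change in how reads were divided between the paralogs was not tested.

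In antigen replicate 3, 100% of the X-linked genes above 0 in the other 8 libraries were listed at 0, against 0.478% of the autosomal ones. Lower depth is argued against, because the estimated depth of this library was the highest of the 3 antigen libraries. The other antigen libraries had 0.977% and 1.05% autosomal zeros, but over genes not required to be above 0 in antigen replicate 3. That wider base raises their shares, so they cannot be set against 0.478%. Values of chromosomes X and Y missing from this column are a candidate explanation for the X and Y zeros, although 1 of 1081 X and Y genes in the table is above 0 there. No biological explanation was tested, and antigen treatment is shared by the 2 libraries that hold X-linked values.

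The hypothesis was that short genes rise first. Its prediction, written before the test, was a shorter span of raised genes than of genes matched on mean FPKM, and was not borne out. Only 2 h of antigen was sampled, so the order in which genes rise could not be seen. Matching used the mean of all 9 libraries, the antigen ones included, and genes at 0 in several libraries were left out. The 767 autosomal genes raised at least 2-fold by antigen on the log2(FPKM + 1) scale, with a span in the GRCm38 annotations (97.2% of the set) had a median genomic span of 29.2 kb. Random lists matched on mean FPKM had a median of 22.1 kb, with a middle 95% of 19.9 to 24.5 kb over 10000 lists (two-sided permutation p = 0.0002, the smallest these lists can give). The raised genes were longer, not shorter, than matched genes. The 310 lowered genes had a median of 23.5 kb against 23.8 kb in matched lists (permutation p = 0.845).

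Each comparison of 3 with 3 libraries allows 10 groupings, too few for a share under 0.05. In each comparison 1 of 10, the real grouping, reached the real number of called genes. For antigen versus IgE these were 7739 against at most 0 in another grouping, for IgE versus untreated 2999 against 0, and for antigen versus untreated 7805 against 1. Every other grouping mixes the treatments within a group, which adds their difference to the spread. Low counts were thus built in, and they are no measure of the calls that arise by chance.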
